A study of Mus musculus with 24 samples.

How the data were processed

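Gene expression was measured by RNA sequencing in 24 libraries of mouse lens, 4 for each of 6 groups. The groups combined 3 conditions (wild type, abbreviated WT, LEGSKO, and LEGSKO treated with buthionine sulfoximine, abbreviated LEGSKO+BSO) with 2 tissues (lens epithelia and cortical fiber cells). Group, tissue and replicate number were taken from the sample titles. The labels give the strain as C57BL/6 and the starting material as total RNA. They name no batch, age or sex, and do not say whether the 4 libraries of a group came from separate animals. All p-values therefore measure the spread between these libraries, which can be partly technical.

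Raw counts per gene were deposited by the authors as 1 table of 24415 Entrez gene identifiers by 24 libraries, and each column was matched to its sample through the labels. Per the submitters' processing notes, CASAVA 1.8, bcl2fastq, TopHat and DESeq were used and the genome build was mm10, also called GRCm38. The notes attach no role or order to these tools. The counting tool, the gene annotation, the strand setting and the library kit are not given in the sources used here. Identifiers were matched to symbols and coordinates with a RefSeq gene table of the same build, and 24334 matched. The remaining 81 held 0.914% of all counts and stayed in the tests. Mitochondrially encoded genes were not analysed here: the table held 0 members of that list. Without strand information, reads of overlapping or antisense genes cannot be told apart, and counts of near-identical copies (Mt1 and Mt2, Aldh1a1 and Aldh1a7, the gamma crystallins, the pseudogene Tubb2a-ps2) are uncertain. No 2 libraries of a group were duplicates: a chi-square test of their counts gave 5.43 to 369 per degree of freedom.

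The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Each tissue was fitted separately, with its 12 libraries in 3 groups sharing 1 estimate of the spread. Library sizes were scaled by TMM, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. Quasi-likelihood F tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The difference between tissues in the response to a condition was tested as an interaction over all 24 libraries in 6 groups. Tissues were never compared directly. Fold changes are fitted values, and counts per M (mega) of scaled total (CPM) are means ± SD of 4 libraries scaled within a tissue. Total counts were 19.3 to 46.6 M per library. The common biological coefficient of variation was 14.2% in epithelia, 12.8% in fibers and 13.7% in the fit of 6 groups.

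The procedure was tested on simulated counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. Against WT, it recovered 62.7%, 91.0% and 100% in LEGSKO epithelia (14919 genes, 10 unchanged genes called). In LEGSKO+BSO epithelia it recovered 68.7%, 89.6% and 100% (14924 genes, 14 unchanged called). The fiber simulations recovered 70.1%, 97.0% and 98.5% for LEGSKO (13336 genes, 5 unchanged called) and 74.6%, 97.0% and 100% for LEGSKO+BSO (13332 genes, 8 unchanged called). For the difference between tissues in LEGSKO (15222 genes) it recovered 50.7%, 86.6% and 100%, with 5 unchanged called. These rates need not hold for all genes tested.

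Of 27 gene lists fixed before the data were examined, 26 had members in the table. They cover glutathione synthesis and thiol redox enzymes, glutathione S-transferases, NRF2 target genes, aldehyde and carbonyl detoxification, epithelial-mesenchymal transition and matrix, lens fiber and crystallin genes, lens epithelial markers, amino acid transporters, ion and water transport, cholesterol synthesis and uptake, and fatty acid metabolism. Others cover the unfolded protein and integrated stress response, heat shock and small chaperones, p53 and apoptosis genes, cell cycle, interferon and complement, inflammatory signalling, metallothioneins and iron handling, and immediate early genes. Markers of other cells formed the lists of red blood cell, immune cell, blood vessel, pigmented iris and ciliary body, retinal neuron and photoreceptor, corneal and conjunctival epithelium, and muscle and stroma markers. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Counts of members are given over all genes tested and adjusted over the list alone.

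Named genes followed a rule set at the same time. Gclc, Gclm and Gss were always reported. For each comparison against WT, candidates had an adjusted p below 0.05, an average log2 CPM of at least 1, groups that did not overlap in CPM, and a symbol other than a Gm number, a clone name or a Rik name. The 6 highest and 6 lowest fold changes among them were taken. Some genes taken by these rules are not reported here. From each list with 3 or more members below 0.05, the 2 members with the smallest adjusted p were added. For LEGSKO+BSO against LEGSKO and for the differences between tissues the 5 highest and 5 lowest were taken, without the overlap criterion for the differences. Markers of other cells and of lens identity could be named in any comparison. List members beyond this rule, the genes shared by both tissues, and Lyz2, Ccr2 and Ncf4 in the last fiber comparison were named after their values were seen.

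Alternatives fixed at the same time were RLE scaling, DESeq2 1.42.0, no filter on low counts, a stricter filter (1 CPM in at least 4 libraries) and leaving out the 16 crystallin genes. Others were the replicate number as a block, only the 2 groups compared, all 24 libraries in 1 fit, an adjusted p below 0.01 for overlaps, and leaving out each library in turn. For the lists they were camera with an estimated correlation and fry. An alternative thinning the LEGSKO+BSO fiber libraries to the mean total of the other fiber libraries, and 1 leaving out both WT fiber library 1 and LEGSKO+BSO epithelial library 4, were chosen after seeing the data. Because both conditions were compared with the same WT libraries, the overlap of their genes was set beside that of independent lists and that with the WT libraries split 2 and 2 in 6 ways. The correlation of fold changes was set beside 40 simulations of unchanged groups, in which 0 genes were called. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.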

Results

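Transcripts were counted in lens epithelia and in cortical fiber cells of wild-type mice, of LEGSKO mice, described by the series as mildly deficient in glutathione, and of LEGSKO mice given buthionine sulfoximine, described as severely deficient. LEGSKO is known as a lens-restricted knockout of Gclc, the catalytic subunit of glutamate-cysteine ligase, which carries out the rate-limiting step of glutathione synthesis. Buthionine sulfoximine (BSO) inhibits the same enzyme. Each of the 6 groups held 4 libraries. Total counts were 20.6 to 24.2 M in WT epithelia, 20.2 to 25.1 M in LEGSKO epithelia and 19.3 to 33.9 M in LEGSKO+BSO epithelia. Among fibers they were 25.7 to 30.01 M in WT, 22.4 to 25.5 M in LEGSKO and 39.0 to 46.6 M in LEGSKO+BSO, so the last group was the most deeply sequenced.

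Crystallins, the structural proteins of the lens, took 12.5% ± 1.62 of counts in WT epithelia, 10.6% ± 2.53 in LEGSKO epithelia and 9.61% ± 2.58 in LEGSKO+BSO epithelia (SD, n = 4). In fibers the shares were 33.9% ± 10.9 in WT, 31.9% ± 2.18 in LEGSKO and 29.6% ± 1.23 in LEGSKO+BSO (SD, n = 4). WT fiber library 1 held 50.1%, against 27.6% to 29.6% in the other WT fiber libraries. Gene adjusted p-values below come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and list adjusted p-values come from camera.

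**Figure D1:**
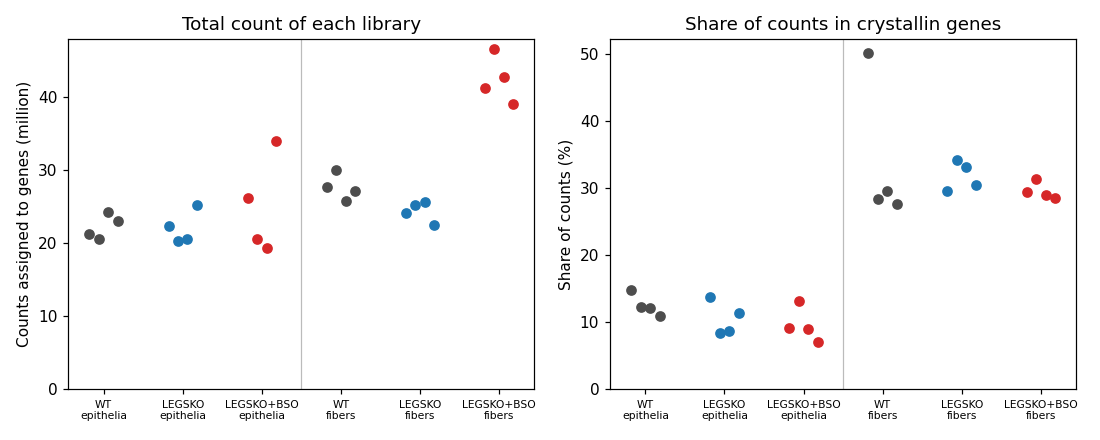
Total counts in M (left) and the percentage of counts in 16 crystallin genes (right) for each of the 24 libraries, 1 point per library, by group. LEGSKO+BSO fiber libraries lie between 39.0 and 46.6 M, and WT fiber library 1 stands at 50.1% crystallin counts.

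Gclc (Entrez 14629, GRCm38 chromosome 9: 77754535 to 77794489) was examined first as the targeted gene. Its CPM in libraries 1 to 4 was 95.6, 71.2, 80.4 and 66.5 in WT epithelia, 70.6, 57.6, 59.9 and 44.8 in LEGSKO epithelia, and 108, 80.9, 89.4 and 63.5 in LEGSKO+BSO epithelia. In fibers it was 133, 71.9, 75.7 and 70.4 in WT, 66.8, 77.8, 81.1 and 76.4 in LEGSKO, and 79.7, 69.6, 72.0 and 79.0 in LEGSKO+BSO. Without the replicate number in the fit, edgeR called Gclc in none of the 6 comparisons, and DESeq2 called it in LEGSKO+BSO against LEGSKO epithelia. With the number as a block, edgeR called it lower in LEGSKO epithelia than in WT and in LEGSKO+BSO epithelia. Against WT fibers its log2 change was -0.22 in LEGSKO and -0.23 in LEGSKO+BSO, and 0.05 and 0.04 without WT fiber library 1. A count over the whole gene also counts exons outside a deleted part, so these levels do not check the knockout.

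LEGSKO epithelia were compared with WT epithelia. Tacr3, the receptor of the tachykinin neurokinin B (Entrez 21338, chromosome 3: 134829007 to 134934581), rose 167-fold, from 0.142 ± 0.119 to 23.8 ± 4.47 CPM (SD, n = 4; log2 fold change 7.38 ± 0.32 SE, adjusted p = 5.397e-09). Cfi, a protease that inactivates complement (Entrez 12630, chromosome 3: 129836727 to 129875332), rose 26.9-fold to 3.88 ± 0.827 CPM (adjusted p = 0.00154). The metallothioneins Mt1 and Mt2, small cysteine-rich metal-binding proteins, rose 4.73-fold (log2 2.24 ± 0.28 SE, adjusted p = 0.00203) and 3.82-fold (log2 1.93 ± 0.42 SE, adjusted p = 0.0420). The urea transporter Slc14a1 rose 5.96-fold, to 5.20 ± 3.92 CPM (adjusted p = 0.0183), and the type I collagen gene Col1a2 rose 5.81-fold, from 18.8 ± 18.6 to 109 ± 24.2 CPM (adjusted p = 0.0237).

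Among genes that fell in LEGSKO epithelia, the homeobox factor Mkx was 3.73-fold lower, at 1.68 ± 0.290 against 6.28 ± 2.72 CPM (SD, n = 4; adjusted p = 0.00911). The A-type potassium channel Kcnd3 was 2.35-fold lower (adjusted p = 0.00644), Ankrd34c 2.27-fold (adjusted p = 0.0101) and the cyclic nucleotide phosphodiesterase Pde10a 2.25-fold (adjusted p = 0.0240). The IKK-related kinase Ikbke was 2.15-fold lower, at 4.07 ± 0.696 against 8.78 ± 1.57 CPM (adjusted p = 0.0141), and the ephrin receptor Ephb2 2.12-fold lower (adjusted p = 0.00364). In all, 127 of 15089 genes were called, 88 higher and 39 lower, of which 20 were at least 2-fold higher and 6 at least 2-fold lower. Gclc (log2 -0.43 ± 0.16 SE, adjusted p = 0.224), its modifier subunit Gclm (log2 0.04 ± 0.18 SE, adjusted p = 0.942) and glutathione synthetase Gss (log2 -0.15 ± 0.18 SE, adjusted p = 0.744) were not called. With the replicate number as a block, Gclc was called.

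Lists of redox and detoxification genes were higher as sets in LEGSKO epithelia at the preset correlation, though few members were called. Of 32 tested aldehyde and carbonyl detoxification genes, 2 rose (camera adjusted p = 0.00161, adjusted p = 0.294 with an estimated correlation). They were the aldose reductase Akr1b3 1.38-fold (adjusted p = 0.00983) and Akr1b10 2.12-fold (adjusted p = 0.0343). Adjusted over the list alone, 6 were higher and 1 lower. Of 31 NRF2 target genes, 1 rose, the oxidative stress-induced growth inhibitor Osgin1 (1.76-fold, adjusted p = 0.0372). Adjusted over the list alone, 3 were higher (camera adjusted p = 0.00265, adjusted p = 0.377 with an estimated correlation). Nqo1 (adjusted p = 0.290) and Hmox1 (adjusted p = 0.220) of this list were not called. Among 40 glutathione and thiol redox genes 0 were called over all genes and 10 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00265, adjusted p = 0.377 with an estimated correlation). For 22 glutathione S-transferases these counts were 0, 1 and 0 (camera adjusted p = 0.0201, adjusted p = 0.321 with an estimated correlation). Of 18 metallothionein and iron genes, Mt1 and Mt2 rose, with 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0215, adjusted p = 0.316 with an estimated correlation).

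Lens fiber and crystallin genes were lower as a set in LEGSKO epithelia, with a median log2 change of -0.41 over 36 genes (camera adjusted p = 1.19e-07, adjusted p = 0.414 with an estimated correlation). Of these, 1 fell over all genes, the RNA-binding protein gene Caprin2 (1.41-fold lower, adjusted p = 0.0420), and 5 were lower adjusted over the list alone. Cell cycle genes (39 tested, 0 called by either adjustment) had camera adjusted p = 0.0255 downward, and adjusted p = 0.639 with an estimated correlation. Immediate early genes (18 tested, 0 called, 2 higher and 6 lower adjusted over the list alone) had camera adjusted p = 0.0485 downward, and adjusted p = 0.377 with an estimated correlation.

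Lists of markers of other cells were also called in LEGSKO epithelia. Corneal and conjunctival epithelium markers were higher, with a median log2 change of 0.59 over 6 genes (camera adjusted p = 1.16e-06, adjusted p = 0.0209 with an estimated correlation). The keratins Krt15 (2.54-fold, 59.8 ± 8.25 against 23.5 ± 7.30 CPM, SD, n = 4, adjusted p = 0.00364) and Krt19 (1.65-fold, adjusted p = 0.0101) rose, and 4 of the 6 were higher adjusted over the list alone. Immune cell markers (12 tested, 0 called, 1 lower adjusted over the list alone) had a median of -0.86 (camera adjusted p = 0.0144, adjusted p = 0.496 with an estimated correlation). Retinal neuron and photoreceptor markers (22 tested, 0 called) had a median of -0.43 (camera adjusted p = 0.0253, adjusted p = 0.732 with an estimated correlation). Of pigmented iris and ciliary body markers, Trpm1 rose 1.25-fold (adjusted p = 0.0279; list adjusted p = 0.725).

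The other lists were not called in this comparison. The epithelial-mesenchymal transition and matrix list (49 tested, adjusted p = 0.671) held 1 gene that rose, Col1a2, and 1 that fell, Tgfb1 (1.46-fold lower, adjusted p = 0.00944). With adjustment over the list alone, 4 were higher and 5 lower. Its median was -0.07, its mean 0.01 and its test downward. Lens epithelial markers (adjusted p = 0.409) had 1 lower gene, the Wnt antagonist Sfrp1 (1.34-fold lower, adjusted p = 0.0220). Ion and water transport (adjusted p = 0.0555) had the potassium channel Kcnj13 higher (2.55-fold, adjusted p = 0.0361). Cholesterol genes (adjusted p = 0.0570) had the efflux transporter Abcg1 higher (1.77-fold, adjusted p = 0.0420). Fatty acid metabolism (adjusted p = 0.713) had lipoprotein lipase Lpl higher (2.13-fold, 225 ± 39.6 against 106 ± 22.3 CPM, adjusted p = 0.00530). Interferon and complement genes (adjusted p = 0.0555) had 1 lower member, Serping1 (1.38-fold lower, adjusted p = 0.0363). No member was called among amino acid transporters (list adjusted p = 0.738; median 0.02, mean -0.11, test downward), the unfolded protein response (0.612), heat shock (0.528), p53 (0.256), inflammatory signalling (0.738), or red blood cell (0.826), blood vessel (0.956) and muscle and stroma markers (0.604).

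Leaving out 1 library changed the count of 127 by over 1.5 times without LEGSKO epithelia 2 (53), 3 (49) or 4 (54) and without WT epithelia 2 (40). Tacr3, Cfi, Mt1, Mkx, Kcnd3 and Ephb2 kept their calls without any 1 library. Slc14a1 lost it without WT epithelia 2 or 4 (highest adjusted p = 0.0578), and Ankrd34c without WT epithelia 2 (0.0514). Col1a2, Mt2, Pde10a and Ikbke lost it without any of LEGSKO epithelia 2, LEGSKO epithelia 3 or WT epithelia 2, among others (highest adjusted p = 0.126). Without WT epithelia 1 the fold was 58.9 for Cfi and 10.7 for Col1a2, and without LEGSKO epithelia 3 it was 3.74 for Slc14a1. Among the lists, S-transferases and immune markers lost their calls without WT epithelia 3 (adjusted p = 0.137 for each), and metallothionein and iron genes without LEGSKO epithelia 3 or WT epithelia 4 (highest 0.0649). Cell cycle genes lost it without LEGSKO epithelia 1 or 4 or WT epithelia 1 or 4 (highest 0.153), and immediate early genes without LEGSKO epithelia 2 or 3 or WT epithelia 1 or 2 (0.296). Retinal markers lost it without LEGSKO epithelia 2 or 4 or WT epithelia 1 or 4 (0.552).

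LEGSKO+BSO epithelia were compared with WT epithelia. Tacr3 was again far higher, at 19.3 ± 3.19 CPM (SD, n = 4; 136-fold, adjusted p = 1.085e-08), and Cfi rose 25.4-fold (adjusted p = 0.00121). Mt1 rose 6.85-fold, to 11.7 ± 3.83 CPM (adjusted p = 0.000257), Mt2 6.27-fold (adjusted p = 0.00730) and Slc14a1 6.54-fold (adjusted p = 0.0129). Serpina3n, a secreted protease inhibitor (Entrez 20716, chromosome 12: 104406646 to 104414334), rose 9.24-fold with a wide spread, 69.0 ± 65.8 against 7.51 ± 1.38 CPM (adjusted p = 0.0110). The matrix genes Col1a2 (4.59-fold, adjusted p = 0.0430) and Tgfbi (3.60-fold, adjusted p = 0.0391) also rose.

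Among lower genes in LEGSKO+BSO epithelia, the A-type potassium channels Kcnd3 and Kcnd1 were 2.94-fold (5.02 ± 0.785 against 14.7 ± 4.38 CPM, SD, n = 4, adjusted p = 0.00122) and 2.74-fold lower (adjusted p = 0.0115). Kctd12b (2.59-fold lower, adjusted p = 0.0452), the exchange factor Rasgef1b (2.30-fold, adjusted p = 0.0202), the nuclear receptor Nr1h5 (2.10-fold, adjusted p = 0.0305) and the deacetylase Hdac9 (2.09-fold, adjusted p = 0.0133) fell as well. The count was 177 of 15089, 120 higher and 57 lower, with 29 at least 2-fold higher and 7 at least 2-fold lower. Gclc (log2 0.12 ± 0.16 SE, adjusted p = 0.766), Gclm (log2 0.28 ± 0.18 SE, adjusted p = 0.493) and Gss (log2 -0.17 ± 0.18 SE, adjusted p = 0.704) were not called.

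Of 34 cholesterol synthesis and uptake genes 4 were called in LEGSKO+BSO epithelia, and the list was not (adjusted p = 0.398; median -0.05, mean 0.03, test downward). Insig1, which holds the regulator of sterol synthesis in the endoplasmic reticulum, fell from 253 ± 25.2 to 162 ± 15.8 CPM (SD, n = 4; 1.56-fold lower, adjusted p = 0.0159). HMG-CoA synthase Hmgcs1 (1.45-fold lower, adjusted p = 0.0238) and squalene synthase Fdft1 (1.36-fold lower, adjusted p = 0.0498) fell, and the cholesterol exporter Abca1 rose 1.41-fold (adjusted p = 0.0442). With adjustment over the list alone, 5 were higher and 6 lower. Of 31 NRF2 target genes, Osgin1 (2.20-fold, adjusted p = 0.00533) and G6pdx, the entry enzyme of the pentose phosphate pathway (1.38-fold, adjusted p = 0.0391), rose. Adjusted over the list alone, 5 were higher (camera adjusted p = 1.04e-05, adjusted p = 0.342 with an estimated correlation). Nqo1 (0.552), Hmox1 (0.904), the cystine transporter Slc7a11 (0.263) and Txnrd1 (0.2503) had these adjusted p-values and were not called. In the metallothionein and iron list of 18, Mt1, Mt2 and the ferrireductase Steap3 (2.09-fold, adjusted p = 0.0118) rose and the transferrin receptor Tfrc fell (1.30-fold lower, adjusted p = 0.0258). Adjusted over the list alone, 4 were higher and 2 lower (camera adjusted p = 0.00167, adjusted p = 0.202 with an estimated correlation).

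The lens epithelial transcription factor gene Foxe3 rose 1.97-fold, to 480 ± 40.5 from 244 ± 50.1 CPM (SD, n = 4; adjusted p = 0.00765), and the growth factor receptor Pdgfra fell (1.81-fold lower, adjusted p = 0.0391), in a list of 25 that was not called (adjusted p = 0.680). Lens fiber and crystallin genes had a median log2 change of -0.38 (36 tested, 0 called by either adjustment; camera adjusted p = 1.04e-05, adjusted p = 0.690 with an estimated correlation). With crystallin genes left out the camera adjusted p was 0.0850. Corneal markers were higher here too, with a median of 0.94 over 6 genes and 4 higher adjusted over the list alone (camera adjusted p = 1.01e-05, adjusted p = 0.0390 with an estimated correlation). Krt15 rose 2.20-fold (adjusted p = 0.00852) and Krt19 1.48-fold (adjusted p = 0.0421). Retinal markers had a median of -1.32 (22 tested, 0 called; camera adjusted p = 0.000421, adjusted p = 0.690 with an estimated correlation). Among lists that were not called, the glutathione list held Gpx4 (1.46-fold higher, adjusted p = 0.0480), the S-transferases Gsto1 (1.39-fold higher, adjusted p = 0.0314), and the aldehyde list Aldh3a1 (2.08-fold, adjusted p = 0.0436) and Akr1b3 (1.27-fold, adjusted p = 0.0452).

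Leaving out 1 library moved the count of 177 by over 1.5 times without LEGSKO+BSO epithelia 1 (41), 2 (324), 3 (56) or 4 (76) and without WT epithelia 2 (56) or 3 (114). Tacr3, Cfi, Mt1, Mt2, Slc14a1 and Kcnd3 kept their calls without any 1 library. Serpina3n lost it without WT epithelia 2 (adjusted p = 0.0530), Hdac9 without LEGSKO+BSO epithelia 1 (0.0625), Kcnd1 without LEGSKO+BSO epithelia 1 or 3 (0.0552), and Rasgef1b without LEGSKO+BSO epithelia 1 or WT epithelia 2 (0.0891). Insig1, Hmgcs1, Tgfbi, Col1a2, Nr1h5 and Kctd12b lost it without LEGSKO+BSO epithelia 1 or 3, among others (highest adjusted p = 0.149). The fold of Serpina3n was 5.03 without LEGSKO+BSO epithelia 4. Without WT epithelia 1 that of Tacr3 was 205, of Cfi 56.1 and of Col1a2 8.53.

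The added effect of BSO in the epithelium was taken from LEGSKO+BSO against LEGSKO epithelia. Serpina3n (9.69-fold, 69.0 ± 65.8 against 7.17 ± 2.53 CPM, SD, n = 4, adjusted p = 0.0208) and Tgfbi (7.67-fold, 7.55 ± 4.28 against 0.989 ± 0.174 CPM, adjusted p = 0.0143) rose. So did Gpnmb, a glycoprotein of pigment cells and macrophages (6.56-fold, 27.3 ± 24.4 against 4.19 ± 1.29 CPM, adjusted p = 0.0248), the melanin synthesis enzyme Dct (6.10-fold, 6.26 ± 1.65 against 1.03 ± 0.620 CPM, adjusted p = 0.0165) and the calcium pump Atp2b2 (2.25-fold, adjusted p = 0.0143). Nr1h5 (2.39-fold lower, adjusted p = 0.0214), the glycosyltransferase Mgat5b (2.02-fold lower, adjusted p = 0.0356), the glypican Gpc5 (1.93-fold lower, adjusted p = 0.0467), Lpl (1.73-fold lower, 130 ± 20.9 against 225 ± 39.6 CPM, adjusted p = 0.0364) and Gas2 (1.69-fold lower, adjusted p = 0.0214) fell. Of 15089 genes 109 were called, 49 higher and 60 lower, with 7 at least 2-fold higher and 2 at least 2-fold lower. Gclc (log2 0.56 ± 0.16 SE, adjusted p = 0.105), Gclm (log2 0.24 ± 0.18 SE, adjusted p = 0.466) and Gss (log2 -0.02 ± 0.18 SE, adjusted p = 0.965) were not called. Gclc was called by DESeq2 and by edgeR with the replicate number as a block.

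Ion and water transport genes were higher as a set after BSO (52 tested; camera adjusted p = 0.00236, adjusted p = 0.570 with an estimated correlation). Atp2b2 and the calcium channel subunit Cacna1c (1.72-fold, adjusted p = 0.0428) rose, and 3 were higher adjusted over the list alone. Unfolded protein response genes (38 tested, 0 called by either adjustment) had camera adjusted p = 0.0298 upward, and adjusted p = 0.570 with an estimated correlation. Foxe3 rose 1.99-fold (adjusted p = 0.0165), and the connexin Gja1 was 1.32-fold lower (adjusted p = 0.0428). Tgfb1 rose 1.52-fold (adjusted p = 0.0143) beside Tgfbi in the matrix list, which was not called (adjusted p = 0.149). Lens fiber genes as a list were not called (adjusted p = 0.581; median -0.10, mean 0.00, test upward).

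Immune cell markers were called as a list after BSO in the epithelium at the preset correlation, but not with the stricter filter (adjusted p = 0.0532). Their median log2 change was 1.72 over 12 genes, of which 0 were called over all genes and 4 higher adjusted over the list alone (camera adjusted p = 0.000714, adjusted p = 0.570 with an estimated correlation). The macrophage lysozyme gene Lyz2 stood at 2.88 ± 2.11 against 0.769 ± 0.175 CPM (SD, n = 4; adjusted p = 0.1004) and the complement gene C1qa at 0.985 ± 0.855 against 0.149 ± 0.108 CPM (adjusted p = 0.134). Of 13 pigmented iris and ciliary body markers Dct rose (list adjusted p = 0.222), while Tyr (adjusted p = 0.204), Tyrp1 (0.209), Pmel (0.396) and Mitf (0.759) were not called.

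Each single library changed the count of 109 by over 1.5 times. It was 50, 0, 19 and 0 without LEGSKO epithelia 1 to 4 in turn, and 0, 442, 0 and 15 without LEGSKO+BSO epithelia 1 to 4 (edgeR; unadjusted p below 0.05 for 2821, 2293, 2361 and 2482 genes where the count was 0, and 636 genes by DESeq2 with all libraries). All 10 named genes lost their calls without LEGSKO epithelia 2 or 4 or LEGSKO+BSO epithelia 1 or 3 (highest adjusted p = 0.127). Without LEGSKO+BSO epithelia 4 the fold was 5.27 for Serpina3n and 3.71 for Gpnmb. The unfolded protein response list lost its call without LEGSKO epithelia 1 or 4 or LEGSKO+BSO epithelia 1 or 4 (highest adjusted p = 0.0869).

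**Figure D2:**
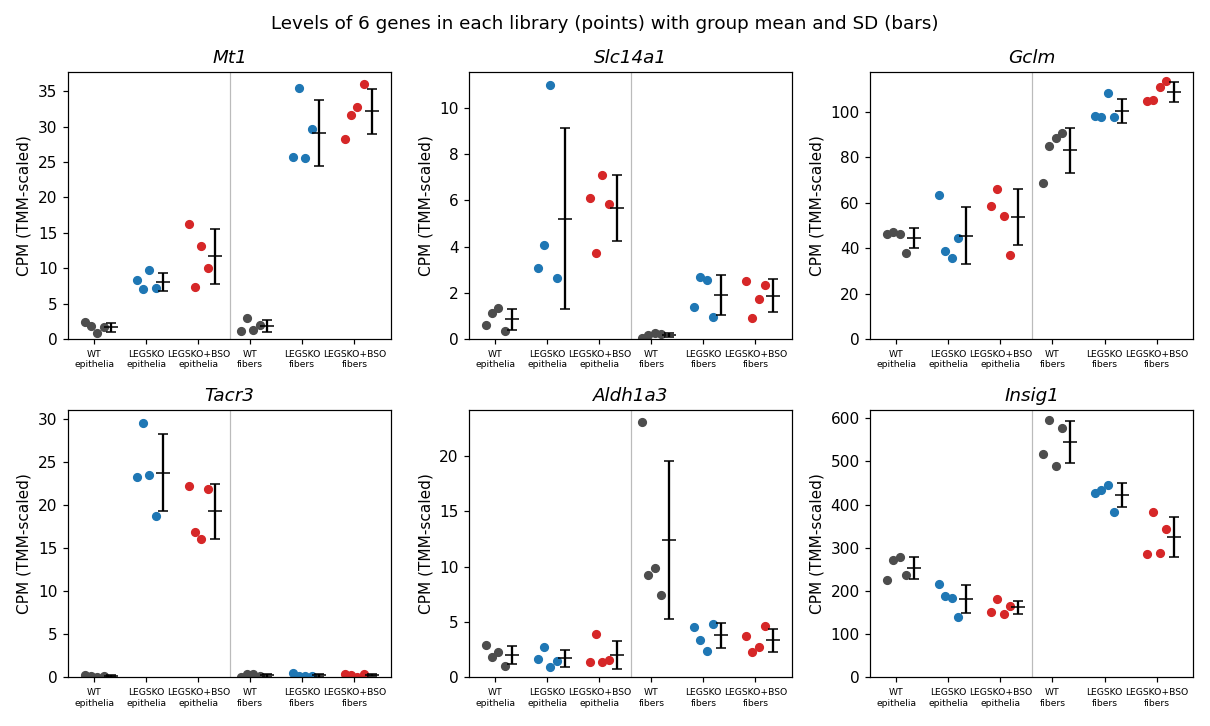
CPM, scaled within a tissue, of Mt1, Slc14a1, Gclm, Tacr3, Aldh1a3 and Insig1 by group, with 1 point per library and a black bar beside each group for its mean ± SD (n = 4). WT fiber library 1 holds 23.03 CPM of Aldh1a3, and LEGSKO epithelial library 3 holds 10.998 CPM of Slc14a1.

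LEGSKO fibers were compared with WT fibers. Mt1 (Entrez 17748, chromosome 8: 94178883 to 94180327) rose 14.96-fold, from 1.86 ± 0.865 to 29.1 ± 4.64 CPM (SD, n = 4; log2 3.90 ± 0.21 SE, adjusted p = 9.004e-08). The calcium-binding protein Cabp5 rose 4.99-fold, to 20.1 ± 4.12 from 4.09 ± 1.09 CPM (adjusted p = 5.442e-05). So did the kinase Pak7 4.62-fold (adjusted p = 0.0439) and clarin Clrn1 4.32-fold (adjusted p = 0.000658). Edaradd, an adaptor of the ectodysplasin receptor, rose 3.40-fold (adjusted p = 0.0233). The retinaldehyde dehydrogenases went in opposite directions. Aldh1a1 rose 2.03-fold, to 242 ± 37.5 from 119 ± 24.8 CPM (adjusted p = 0.00192). Aldh1a3 was 3.23-fold lower, at 3.81 ± 1.12 against 12.5 ± 7.31 CPM (adjusted p = 0.0222).

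Other genes that fell in LEGSKO fibers were the metalloprotease Amz1 (3.13-fold lower, adjusted p = 0.00192), the pseudogene Tubb2a-ps2 (2.34-fold, adjusted p = 0.0484) and Fbxw21 (1.91-fold, adjusted p = 0.00186). So were the flippase Atp8a2 (1.88-fold, adjusted p = 0.0495) and the p53 ubiquitin ligase Mdm2 (1.33-fold, adjusted p = 0.0227). Of 13436 genes 220 were called, 147 higher and 73 lower, with 43 at least 2-fold higher and 10 at least 2-fold lower. Gclc (log2 -0.22 ± 0.16 SE, adjusted p = 0.572), Gclm (log2 0.27 ± 0.08 SE, 100 ± 5.15 against 83.2 ± 9.45 CPM, adjusted p = 0.105) and Gss (log2 0.06 ± 0.09 SE, adjusted p = 0.812) were not called.

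Glutathione S-transferases were higher as a set in LEGSKO fibers (20 tested, 1 higher over all genes and 4 adjusted over the list alone; camera adjusted p = 0.0273, adjusted p = 0.491 with an estimated correlation). The microsomal enzyme Mgst1 led them (119 ± 9.90 against 70.9 ± 8.31 CPM, SD, n = 4, adjusted p = 0.00121). Glutathione peroxidase Gpx1 rose 1.34-fold (adjusted p = 0.01002) and the NRF2 target Pir 1.66-fold (adjusted p = 0.0278), in lists that were not called (adjusted p = 0.142 and 0.0515). The metallothionein and iron list had Mt1 and transferrin Trf higher (Trf 3.27-fold, adjusted p = 0.000851) among 17. Over the list alone 3 were higher (camera adjusted p = 0.0273 upward, adjusted p = 0.491 with an estimated correlation), although the median of the list was -0.05 and the mean -0.02. Cholesterol genes were lower as a set, with a median of -0.19 over 33 genes (camera adjusted p = 0.00914, adjusted p = 0.491 with an estimated correlation) and 3 higher and 9 lower adjusted over the list alone. The 2 called over all genes rose, among them Abcg1 (8.68-fold, 0.998 ± 0.416 against 0.102 ± 0.0994 CPM, adjusted p = 0.0336).

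Unfolded protein and integrated stress response genes were lower as a set in LEGSKO fibers (36 tested; camera adjusted p = 0.0145, adjusted p = 0.491 with an estimated correlation), with 2 higher and 9 lower adjusted over the list alone. Over all genes the factor Atf5 rose 1.30-fold (adjusted p = 0.0404) and Cebpb was 4.69-fold lower (adjusted p = 0.0453). Of 36 lens fiber genes (list adjusted p = 0.142), the connexin Gje1 rose 1.37-fold (adjusted p = 0.0191) and Caprin2 was 1.501-fold lower (adjusted p = 0.00610). Vimentin (Vim) rose 1.41-fold (adjusted p = 0.0270), smooth muscle actin Acta2 1.31-fold (adjusted p = 0.0345) and Gadd45g 1.62-fold (adjusted p = 0.0257). Of 24 lens epithelial markers 2 rose over all genes and 5 adjusted over the list alone, in a list that was not called (adjusted p = 0.378; median -0.06, mean -0.02, test upward). The 2 were Tfap2a (1.32-fold, adjusted p = 0.00489) and Mab21l1 (1.31-fold, adjusted p = 0.0191). Of 10 retinal markers Pde6b rose 2.27-fold (adjusted p = 0.0392; list adjusted p = 0.0515). Of 3 immune markers tested 0 were called (list adjusted p = 0.713). Aldh1a7, a close relative of Aldh1a1, rose 1.94-fold (adjusted p = 0.0103).

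Without WT fiber library 1 the count of 220 became 591. It was 96, 144 and 96 without WT fibers 2, 3 and 4, and 110, 61 and 125 without LEGSKO fibers 2, 3 and 4. Mt1, Cabp5, Clrn1, Amz1, Fbxw21 and Aldh1a1 kept their calls without any 1 library. Aldh1a7 lost it without LEGSKO fibers 3 (adjusted p = 0.0542), and Aldh1a3 and Mdm2 without LEGSKO fibers 2 or 3 (highest 0.104). Edaradd, Vim and Gadd45g lost it without LEGSKO fibers 3 or WT fibers 2, 3 or 4, among others (0.117), and Pak7, Tubb2a-ps2 and Atp8a2 without any library except WT fibers 1 (0.146). The fold of Edaradd was 5.25 without WT fibers 1. The S-transferase list lost its call without LEGSKO fibers 2 or WT fibers 3 or 4 (highest adjusted p = 0.149), and the metallothionein and iron list without WT fibers 3 or 4 (0.117).

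LEGSKO+BSO fibers were compared with WT fibers. Mt1 rose 16.5-fold, to 32.0 ± 3.20 CPM (SD, n = 4; adjusted p = 4.742e-08). Higher too were Cabp5 6.28-fold (adjusted p = 1.078e-05), Clrn1 3.70-fold (adjusted p = 0.000913), Trf 3.52-fold (adjusted p = 0.000280) and Tmtc1 3.43-fold (adjusted p = 2.009e-05). Gclm, the modifier subunit of glutamate-cysteine ligase (Entrez 14630, chromosome 3: 122245487 to 122267215), rose 1.30-fold, to 108 ± 4.43 from 83.2 ± 9.45 CPM (log2 0.38 ± 0.08 SE, adjusted p = 0.0148). Gclc (log2 -0.23 ± 0.16 SE, adjusted p = 0.443) and Gss (log2 0.00 ± 0.09 SE, adjusted p = 0.988) were not called. Ermap, an erythroid membrane protein gene, was 5.24-fold lower, at 3.69 ± 1.35 against 19.9 ± 22.8 CPM (adjusted p = 0.0212). The small chaperone Hspb8 (3.99-fold lower, adjusted p = 0.0122), Aldh1a3 (3.70-fold, adjusted p = 0.00535), Tubb2a-ps2 (3.24-fold, adjusted p = 0.00427), Dgat2 of triglyceride synthesis (3.09-fold, adjusted p = 0.0316) and the amylase gene Amy2a5 (2.98-fold, adjusted p = 0.00373) also fell. Of 13436 genes 742 were called, 410 higher and 332 lower, with 64 at least 2-fold higher and 45 at least 2-fold lower.

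Cholesterol synthesis and uptake genes were lower as a set in LEGSKO+BSO fibers. Of 33, 8 fell and 3 rose over all genes, and 18 were lower and 5 higher adjusted over the list alone (median log2 change -0.27; camera adjusted p = 5.56e-06, adjusted p = 0.338 with an estimated correlation). Insig1 fell to 324 ± 46.9 from 546 ± 48.7 CPM (SD, n = 4; 1.69-fold lower, adjusted p = 0.000913). The synthesis enzymes Hmgcs1 (1.79-fold lower, adjusted p = 0.0258), Idi1 (1.85-fold, adjusted p = 0.0407), Fdft1 (1.505-fold, adjusted p = 0.0184), Msmo1 (adjusted p = 0.00345) and Dhcr7 (1.93-fold, adjusted p = 0.0495) were lower. The 3 that rose were the cholesterol exporters Abca1 (2.64-fold, adjusted p = 0.0106) and Abcg1 (11.6-fold, 1.33 ± 0.720 against 0.102 ± 0.0994 CPM, adjusted p = 0.00746), and the ubiquitin ligase Mylip (1.40-fold, adjusted p = 0.0460). Fatty acid genes as a list were not called (adjusted p = 0.981), with Elovl4 1.72-fold lower (adjusted p = 0.0112), Cd36 3.93-fold lower (adjusted p = 0.0405), Fasn 1.36-fold higher (adjusted p = 0.0450) and Acsl1 1.25-fold higher (adjusted p = 0.0443).

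Several antioxidant genes rose in LEGSKO+BSO fibers. Of 31 NRF2 target genes 4 rose, Gclm, Srxn1, Pir (1.51-fold, adjusted p = 0.0341) and the transketolase Tkt (1.24-fold, adjusted p = 0.0387). Over the list alone 6 were higher (camera adjusted p = 0.0289, adjusted p = 0.338 with an estimated correlation). Sulfiredoxin Srxn1 stood at 9.64 ± 0.350 against 6.97 ± 0.448 CPM (SD, n = 4; 1.38-fold, adjusted p = 0.0106). Nqo1 (0.729), Hmox1 (0.274), Slc7a11 (0.780) and Txnrd1 (0.863) had these adjusted p-values and were not called. Of 34 glutathione and thiol redox genes 6 rose and 0 fell, with 8 higher and 4 lower adjusted over the list alone (list adjusted p = 0.0829). Gpx1 reached 101 ± 6.53 from 68.6 ± 1.13 CPM (1.47-fold, adjusted p = 0.000953) and the thioredoxin inhibitor Txnip rose 1.70-fold (adjusted p = 0.00225). Mgst1 rose 1.62-fold (adjusted p = 0.00120) among S-transferases (list adjusted p = 0.0608). Aldh1a1 rose 2.33-fold, to 279 ± 33.7 CPM (adjusted p = 0.000280), in the aldehyde list, of which 3 rose and 2 fell (list adjusted p = 0.440). In the metallothionein and iron list Mt1 and Trf rose (17 tested, 2 higher and 2 lower adjusted over the list alone; median -0.06, mean 0.12, camera adjusted p = 0.0289 upward, adjusted p = 0.338 with an estimated correlation).

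Several protein folding genes fell in LEGSKO+BSO fibers. Of 36 unfolded protein response genes 4 fell, the endoplasmic reticulum chaperone BiP (Hspa5, 238 ± 29.4 against 333 ± 59.7 CPM, SD, n = 4, 1.39-fold lower, adjusted p = 0.0233), Hsp90b1 (1.20-fold lower, adjusted p = 0.0304), Pdia4 and Pdia6. Atf5 rose 1.30-fold (adjusted p = 0.0212), and 13 were lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0289, adjusted p = 0.622 with an estimated correlation). Of 21 heat shock genes Hspb8, Dnajb4 and Hspa4l (1.28-fold lower, adjusted p = 0.0152) fell, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0289, adjusted p = 0.622 with an estimated correlation). Interferon and complement genes were lower, with a median of -0.36 over 22 genes and 4 lower adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.338 with an estimated correlation). Among them H2-K1 fell (1.36-fold lower, adjusted p = 0.0355). Of 28 p53 and apoptosis genes (list adjusted p = 0.413), Plk3 (3.04-fold, adjusted p = 0.0155), Phlda3 (1.66-fold, adjusted p = 0.0135) and Bcl2 (1.24-fold, adjusted p = 0.0218) rose. The death receptor Fas (1.83-fold lower, adjusted p = 0.0138) and Mdm2 (1.32-fold lower, adjusted p = 0.0126) fell.

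In the matrix list of 34 (adjusted p = 0.0608), Sparc fell to 533 ± 88.4 from 884 ± 182 CPM (SD, n = 4; 1.66-fold lower, adjusted p = 0.00965), as did Itgb1 and Tgfbr1, while Acta2 (1.30-fold, adjusted p = 0.0192) and Vim rose. Lens fiber and crystallin genes had a median of -0.31 (36 tested, 2 higher and 1 lower over all genes, 2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.983 with an estimated correlation). Caprin2 fell to 115 ± 10.9 from 203 ± 28.6 CPM (1.76-fold lower, adjusted p = 0.000285) and Gje1 rose 1.29-fold (adjusted p = 0.0272). This list call moved with the high crystallin share of WT fiber library 1. Without that library the direction turned upward, with adjusted p = 0.400. Immune cell markers were higher (3 tested; camera adjusted p = 0.000914, adjusted p = 0.0770 with an estimated correlation), with Lyz2 6.72-fold higher (adjusted p = 6.937e-05), the 1 called by either adjustment. The source of these Lyz2 reads was not settled.

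The count of 742 became 293, 285 and 308 without LEGSKO+BSO fibers 1, 3 and 4 and 418 without WT fibers 2. Of the 32 genes taken by the rule for naming, 23 kept their calls without any 1 library. Lost calls were those of Hspa4l without LEGSKO+BSO fibers 4 (adjusted p = 0.0559), Acta2 without LEGSKO+BSO fibers 1 or 3 (0.0643), and Ermap and Dgat2 without LEGSKO+BSO fibers 1, 3 or 4 (0.0948). So were those of Hspa5 without LEGSKO+BSO fibers 1, 2 or 4 (0.0768), Atf5 without LEGSKO+BSO fibers 1 or 3 or WT fibers 3 (0.0717), Gje1 without LEGSKO+BSO fibers 1 or 3 or WT fibers 2, 3 or 4 (0.0813), and Cd36 without any except LEGSKO+BSO fibers 2 and WT fibers 2 (0.118). Without WT fiber library 1, Ermap was 2.31-fold and Dgat2 1.84-fold lower. The heat shock list lost its call without WT fibers 1 (adjusted p = 0.166), WT fibers 3 (0.0501), LEGSKO+BSO fibers 2 (0.231) or LEGSKO+BSO fibers 4 (0.0829). The unfolded protein response list lost it without LEGSKO+BSO fibers 2 or 4 or WT fibers 2 (highest 0.185), and the lens fiber list also without LEGSKO+BSO fibers 4 (0.0586). NRF2 targets (highest 0.0796) and metallothionein and iron genes (highest 0.107) lost it without LEGSKO+BSO fibers 4 or WT fibers 3 or 4.

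The added effect of BSO in fiber cells was taken from LEGSKO+BSO against LEGSKO fibers, where 4 of 13436 genes were called (edgeR, with 1412 at an unadjusted p below 0.05 and 70 called by DESeq2). Lyz2, a lysozyme of macrophages and neutrophils, rose 6.68-fold, from 0.442 ± 0.0880 to 2.97 ± 0.528 CPM (SD, n = 4; log2 2.74 ± 0.26 SE, adjusted p = 0.000383). The chemokine receptor Ccr2 (adjusted p = 0.0221) and the phagocyte oxidase component Ncf4 (adjusted p = 0.0370) were higher. Lyz2, Ccr2 and Ncf4 are myeloid transcripts that may be reads of another sample. The LEGSKO+BSO fiber libraries were also sequenced more deeply (39.0 to 46.6 M counts against 22.4 to 25.5 M). Their rise, and that of the immune cell list that includes Lyz2, can therefore not be assigned to BSO. Mir703 was 1.55-fold lower, at 11.1 ± 0.780 against 17.2 ± 2.67 CPM (adjusted p = 0.0370). Immune cell markers were the list that held at both correlations (3 tested, median 1.42, 2 higher adjusted over the list alone; camera adjusted p = 2.41e-08, adjusted p = 0.00407 with an estimated correlation). Cholesterol genes (33 tested, 0 called, 2 lower adjusted over the list alone) had camera adjusted p = 0.0376 downward, and adjusted p = 0.834 with an estimated correlation. Retinal markers (10 tested, 0 called, 3 lower adjusted over the list alone) had camera adjusted p = 0.0340 downward, and adjusted p = 0.792 with an estimated correlation. No member of the glutathione or NRF2 lists was called (list adjusted p = 0.776 for each). Gclc (log2 -0.02, adjusted p = 0.984), Gclm (log2 0.11, adjusted p = 0.667) and Gss (log2 -0.06, adjusted p = 0.849) were not called either. The count of 4 was 7 without LEGSKO fibers 1, 2 without LEGSKO+BSO fibers 4 and 1 without any other single library. Mir703 lost its call without any library except LEGSKO fibers 1 (highest adjusted p = 0.199). The cholesterol list lost its call without LEGSKO fibers 2 or 3 or LEGSKO+BSO fibers 1 or 3 (highest 0.159). Retinal markers lost it without LEGSKO fibers 1 or LEGSKO+BSO fibers 1 or 2 (0.313).

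LEGSKO and LEGSKO+BSO shared genes within each tissue. Both carry the LEGSKO genotype and no WT group had BSO, so the overlap cannot be assigned to deficiency alone. In epithelia 52 genes were called in the same direction in LEGSKO and in LEGSKO+BSO against WT, 43 higher and 9 lower, among them Tacr3, Cfi, Slc14a1, Col1a2, Mt1, Mt2 and Kcnd3. In fibers 150 genes were shared, 112 higher and 38 lower, among them Mt1, Cabp5, Clrn1, Aldh1a1 and Aldh1a3. In either tissue 0 genes were called in opposite directions. Independent lists of these sizes would share 0.847 and 6.29 genes. With the WT libraries split 2 and 2, 7 to 11 genes were shared in epithelia (0.0429 to 0.194 for independent lists) and 38 to 51 in fibers (0.774 to 3.48). Across genes, which are not independent replicates, fold changes of the 2 conditions correlated at r = 0.506 in epithelia (0.491 in simulations, covariance 0.0543 against 0.0324) and r = 0.681 in fibers (0.508 in simulations, covariance 0.0801 against 0.0257).

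Whether a response differed between tissues was tested directly. The response of Tacr3 differed between tissues. The difference, fibers minus epithelia, was -7.36 ± 0.78 SE on the log2 scale in LEGSKO (0.02 in fibers against 7.38 in epithelia, adjusted p = 2.021e-05) and -6.93 in LEGSKO+BSO (adjusted p = 1.601e-05). Manba, a lysosomal mannosidase, differed in the other direction, by 1.38 ± 0.16 SE in LEGSKO (0.95 in fibers against -0.43 in epithelia, adjusted p = 9.353e-05) and 1.502 ± 0.16 SE in LEGSKO+BSO (adjusted p = 1.601e-05). In LEGSKO, 16 of 15560 genes differed (5 higher in fibers, 11 lower), among them Clrn1 (1.45, adjusted p = 0.0362), the transcription factor Sox4 (1.25, adjusted p = 0.0288) and Amz1 (-2.36, adjusted p = 0.00414). In LEGSKO+BSO 43 differed (25 higher, 18 lower), among them Cabp5 (1.96, adjusted p = 0.0289), Mgat5b (1.59, adjusted p = 0.000449) and the adenylyl cyclase Adcy1 (-1.53, adjusted p = 0.00451). With the replicate number as a block, 7 differed in LEGSKO and 10 in LEGSKO+BSO, and Cabp5 lost its call. Gclc, Gclm and Gss were not called in LEGSKO (adjusted p = 0.861, 0.806 and 0.847) or in LEGSKO+BSO (0.567, 0.886 and 0.785).

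Of the lists, unfolded protein response genes had lower changes in fibers than in epithelia in LEGSKO+BSO (38 tested, 1 lower over all genes, Hspa5, and 1 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.00393, adjusted p = 0.734 with an estimated correlation). Cholesterol genes did so too (34 tested, 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0108, adjusted p = 0.734 with an estimated correlation, and adjusted p = 0.115 at the preset correlation without WT fibers 1). In LEGSKO, lens fiber genes (36 tested, 1 higher adjusted over the list alone, camera adjusted p = 0.0154, adjusted p = 0.875 with an estimated correlation) and immediate early genes (19 tested, 2 higher adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.341 with an estimated correlation) differed upward. Retinal markers did as well, with a median of 1.77 over 22 genes (camera adjusted p = 3.81e-05, adjusted p = 0.875 with an estimated correlation). The lens fiber list lost its call without LEGSKO epithelia 2 or 3, LEGSKO fibers 2, WT epithelia 1 or 2 or WT fibers 2, 3 or 4 (highest adjusted p = 0.274). Immediate early genes lost it without LEGSKO epithelia 2, LEGSKO fibers 2 or 4, WT epithelia 2 or WT fibers 1 or 4 (0.120), and retinal markers without LEGSKO fibers 1 (0.0544). Without 1 library the count of 16 was 25, 4, 6 and 5 for LEGSKO epithelia 1 to 4, 4, 10 and 4 for LEGSKO fibers 1 to 3, 10, 6 and 7 for WT epithelia 2 to 4, and 46, 5 and 6 for WT fibers 1, 2 and 4. That of 43 was 14, 93, 14 and 12 for LEGSKO+BSO epithelia 1 to 4, 15, 18 and 14 for LEGSKO+BSO fibers 1, 3 and 4, 13, 18 and 94 for WT epithelia 2 to 4, and 94 for WT fibers 1. Manba and Tacr3 in both conditions, Amz1 in LEGSKO, and Mgat5b and Adcy1 in LEGSKO+BSO kept their calls without any 1 library. The difference of Tacr3 in LEGSKO was -7.96 without LEGSKO fibers 1. Sox4 and Clrn1 lost them without LEGSKO epithelia 2 or 4 or LEGSKO fibers 1 or 3, among others (highest adjusted p = 0.105), and Cabp5 without LEGSKO+BSO epithelia 1 or 4, among others (0.0766).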

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

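Tests of the share of the distance left without crystallin genes, of the stage of lens growth, of the window around Tacr3, and the alternative that left out 2 libraries were chosen only after the result was seen.

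WT fiber library 1 stood apart from the other WT fiber libraries. Its crystallin share was 50.1% against 27.6% to 29.6%. Of 186 sets of 4 values, 16 held a library far outside the others, and 10 of these were WT fiber library 1, where chance gives about 1 in 20 sets. Its CPM was 133 for Gclc (others 70.4 to 75.7), 10.8 for Edaradd (2.80 to 3.36), 23.03 for Aldh1a3 (7.44 to 9.91), and 12.3 for Atp8a2 (6.65 to 7.30). It was 53.4 for Ermap (8.26 to 9.12), 15.8 for Dgat2 (3.38 to 5.23), 16.1 for Txnip (11.4 to 12.2) and 416 for Hspa5 (293 to 309). Among genes singled out after the values were seen, the matrix gene Bgn stood at 46.7 CPM against 2.37 ± 0.826 (SD, n = 3), the p53 target Cdkn1a at 0 against 3.98 ± 0.487 and Eda2r at 0.439 against 5.84 ± 0.577.

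If crystallin transcripts alone set the library apart, it should rejoin the others without them. Without crystallin genes its mean distance to the other WT fiber libraries was 0.618, where theirs were 0.405 to 0.415. It was 1.504 times the largest of theirs with crystallin genes and 1.49 times without, so 0.969 of the excess was left. The ratio missed the preset bound of 1.5 and the library did not rejoin the others. As 16 genes can hardly move such a mean, the test cannot decide. Another candidate is a lens at another stage of growth, since gamma crystallins mark the early formation of fibers. The median log2 difference of the 6 gamma crystallins A to F was 3.51 and that of 8 alpha and beta crystallins 1.24, a gap of 2.27. The labels give no age and the gamma crystallins are near-identical, so this stays open. A difference between animals or in dissection was not tested.

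Other values far from their group were Gclm at 37.7 CPM in WT epithelia 4 (others 46.0 to 47.01) and at 108 in LEGSKO fibers 3 (97.5 to 98.0), Slc14a1 at 10.998 in LEGSKO epithelia 3 (2.65 to 4.06) and Pde10a at 6.36 in LEGSKO epithelia 1 (3.51 to 3.82). LEGSKO+BSO epithelia 2 held Kcnd1 at 2.66 (1.499 to 1.66) and Col1a2 at 54.1 (92.8 to 99.4).

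Responses that differed between tissues numbered 16 genes in LEGSKO and 43 in LEGSKO+BSO. Of 100 splits of the libraries within tissues, 3 gave at least 16 genes, the real split included. Chance is thus made less likely for LEGSKO, but is not excluded. The highest other split called 447, several times as many, which points to a structure of the samples; what it separates was not tested. For LEGSKO+BSO 6 of 100 splits gave at least 43, and the highest other called 123, so chance cannot be excluded. For the lists it cannot be excluded either: 57 of 100 splits called at least 3 lists in LEGSKO (highest other 10) and 91 of 100 at least 2 in LEGSKO+BSO (highest other 10). With WT fiber library 1 and LEGSKO+BSO epithelial library 4 both left out, 41 genes differed in LEGSKO+BSO, 21 of them among the 43. With the replicate number as a block, 7 genes differed in LEGSKO and 10 in LEGSKO+BSO.

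Fibers minus epithelia, the log2 response to LEGSKO differed for Clrn1 (1.45), Ptprn2 (1.41), Manba (1.38), Sox4 (1.25), Zfp185 (0.56), Tacr3 (-7.36), Amz1 (-2.36), Hmgn3 (-1.04) and Sfxn3 (-0.84). In LEGSKO+BSO it differed for Cabp5 (1.96), Drd4 (1.64), Mgat5b (1.59), Manba (1.502), Glcci1 (1.47), Tacr3 (-6.93), Trim34a (-2.20), Adcy1 (-1.53), Nat8l (-1.26) and Hmgn3 (-1.04). Manba, Tacr3, Amz1, Mgat5b, Adcy1 and Nat8l kept their calls without any 1 library, with Tacr3 in LEGSKO at -7.96 without LEGSKO fibers 1. In LEGSKO, Ptprn2 lost its call in 10 of 16 such fits, Zfp185 in 9, Hmgn3 in 9, Clrn1 in 9, Sox4 in 7 and Sfxn3 in 13 (highest adjusted p = 0.128). In LEGSKO+BSO, Drd4 and Trim34a lost it in 12 each and Cabp5 in 6 (highest adjusted p = 0.0909). Glcci1 lost it without LEGSKO+BSO epithelia 3 or LEGSKO+BSO fibers 1 (0.0569), and Hmgn3 without LEGSKO+BSO fibers 4 or WT epithelia 2 (0.0517).

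Cfi and Manba each lie within 5 Mb of Tacr3 on chromosome 3, and Tacr3 at 167-fold in LEGSKO epithelia invites the question of a chromosome segment of another strain or a transgene nearby. In the 5 Mb on either side of Tacr3, 3 of 46 tested genes were called against WT in both conditions in at least 1 tissue (Manba, Cfi and Tspan5). Windows around 15336 tested genes held 0.885 on average and 5.80% of windows held as many, so this cannot be told apart from chance clustering. Across the genome, the 52 genes shared in epithelia formed 9 neighbouring pairs within 5 Mb against a mean of 6.83 in 10000 random draws (permutation p = 0.230), which leaves segments open there. The 150 shared in fibers formed 29 pairs (random mean 47.9, permutation p = 1). No draw held fewer, so the draws ran too high to test segments. No genotype data were used here, and an effect of glutathione deficiency on Tacr3 itself was not tested apart from the genotype.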

How the results depend on the processing

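The alternatives that thinned the LEGSKO+BSO fibers or left out 2 libraries together were chosen only after the result was seen. Comparisons are given in the order LEGSKO against WT, LEGSKO+BSO against WT and LEGSKO+BSO against LEGSKO. With RLE scaling or without crystallin genes, all 10 counts of genes stayed within 1.5 times. DESeq2 called 440, 551 and 636 genes in epithelia and 500, 1153 and 70 in fibers. It called 77 and 306 for the differences between tissues in LEGSKO and LEGSKO+BSO, and 142 and 332 shared by LEGSKO and LEGSKO+BSO in epithelia and fibers. At an adjusted p below 0.01 the shared genes were 13 and 41, fewer by construction. With only the 2 groups compared, LEGSKO+BSO against WT epithelia had 62 genes, LEGSKO against WT fibers 85, LEGSKO+BSO against WT fibers 417 and LEGSKO+BSO against LEGSKO fibers 56. In 1 fit of all 24 libraries LEGSKO+BSO against LEGSKO had 250 genes in epithelia and 7 in fibers. The latter comparison had 2 genes with LEGSKO+BSO fibers thinned, 14 with no filter and 1 with the stricter filter. LEGSKO+BSO against WT fibers thinned had 674, of which 649 were among the 742. Where not due to fewer samples or genes, the cause was not tested.

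Across genes as a whole, replicate numbers did not clearly pair the libraries within a tissue. Deviations correlated above 0.1 in 2 of 12 same-number pairs in epithelia and 3 of 12 in fibers, and 1 and 3 of 12 libraries were closest to their own number. Gclc in epithelia was an exception, as its CPM ranked by replicate number in the same order in all 3 groups. Across tissues they correlated above 0.1 in 5 of 12 same-number pairs (median 0.0897) and in 7 of 36 other pairs (median -0.0182). All 4 LEGSKO+BSO epithelial libraries correlated best with the fiber library of their own number (0.0805, 0.185, 0.119 and 0.227), as did WT epithelia 1 (0.391) and 3 (0.0702), but not WT epithelia 2 and 4 or any LEGSKO epithelial library, so a shared origin across tissues stays open. With the number as a block, LEGSKO+BSO against LEGSKO epithelia had 46 genes, LEGSKO against WT fibers 143, LEGSKO+BSO against LEGSKO fibers 2, and the differences 7 and 10. With the block, Gclc was called in LEGSKO epithelia against both other groups, and 19 named genes lost their calls. Among the differences these included Ptprn2, Zfp185 and Hmgn3 in LEGSKO and Cabp5, Drd4, Glcci1 and Trim34a in LEGSKO+BSO. Within epithelia they included Kctd12b and Nr1h5 in LEGSKO+BSO against WT, and Mgat5b and Gpc5 in LEGSKO+BSO against LEGSKO. Within fibers they included Tubb2a-ps2, Atp8a2 and Vim in LEGSKO, Dgat2 and Cd36 in LEGSKO+BSO against WT, and Mir703 in LEGSKO+BSO against LEGSKO.

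Leaving out 1 library gave 40 to 183, 41 to 324 and 0 to 442 genes in epithelia, 61 to 591, 285 to 1075 and 1 to 7 in fibers, and 4 to 46 and 12 to 94 for the differences. The cause was not tested. Of 1256 such fits of named genes 940 kept their call status, 297 lost a call and 19 changed sign. The sign changed for Gclc, Gclm and Gss. In fibers Gclc turned from a log2 of -0.22 to 0.05 in LEGSKO and from -0.23 to 0.04 in LEGSKO+BSO without WT fiber library 1, which held 133 CPM of it. The log2 change of Gclm in LEGSKO against WT epithelia ranged from -0.163 to 0.138, of Gclc in LEGSKO+BSO against WT epithelia from -0.0105 to 0.245 and of Gss in LEGSKO+BSO against LEGSKO epithelia from -0.246 to 0.117. In fibers Gclc ranged from -0.310 to 0.0517, -0.322 to 0.0418 and -0.0670 to 0.0227, and Gss from -0.0253 to 0.117, -0.0512 to 0.0401 and -0.114 to 0.0231. Gclm in the difference for LEGSKO+BSO ranged from -0.0421 to 0.217, and was -0.119 without WT fibers 1 and LEGSKO+BSO epithelia 4. Gss in LEGSKO+BSO against WT fibers was 0.00248 without crystallin genes and 0.00719 with no filter. The lens fiber and crystallin list in LEGSKO+BSO against WT fibers had adjusted p = 7.11e-05 to 0.400. Of 352 list tests 289 kept their call, 62 lost it and this 1 reversed.

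Of 39 list calls 3 held with an estimated correlation and 10 with fry, which tests a list alone. The fit of all 24 libraries lost the metallothionein and iron list in LEGSKO epithelia and LEGSKO fibers (adjusted p = 0.0576 and 0.183), 7 lists in LEGSKO+BSO fibers (0.0651 to 0.158) and the cholesterol list in LEGSKO+BSO against LEGSKO fibers (0.0733). The stricter filter lost immediate early genes (0.0706) and immune markers (0.129) in LEGSKO epithelia. For LEGSKO+BSO against LEGSKO it lost the unfolded protein response and immune markers in epithelia (0.0532 each) and cholesterol genes (0.0541) and retinal markers (0.0709) in fibers. With no filter the metallothionein and iron list in LEGSKO fibers (0.148) and interferon genes in LEGSKO+BSO fibers (0.0643) were lost, with RLE immediate early genes in LEGSKO epithelia (0.0508), with 2 groups immune markers in LEGSKO epithelia (0.127), and with the block the difference of immediate early genes in LEGSKO (0.0538). Without crystallin genes the lens fiber list was lost in LEGSKO+BSO epithelia (0.0850) and fibers (0.139). Named genes all kept direction and call with RLE. DESeq2 called Gclc in LEGSKO+BSO against LEGSKO epithelia and Gclm in LEGSKO against WT fibers and lost Ermap. The 1 fit of all 24 libraries lost 13 named calls, Mt2 in LEGSKO epithelia and Gclm in LEGSKO+BSO fibers among them, and the 2-group fits lost 19. These 19 included Col1a2 in both comparisons of epithelia with WT, and Tgfbi, Nr1h5 and Rasgef1b in LEGSKO+BSO epithelia. In LEGSKO fibers they included Edaradd, Aldh1a3, Aldh1a7, Atp8a2, Vim, Mdm2 and Gadd45g. In LEGSKO+BSO fibers they included Ermap, Dgat2, Gje1, Cd36 and Hspa5. Thinning lost Cd36 and Mir703, and the stricter filter Mir703. The share of higher genes moved by over 10 percentage points with DESeq2, to 256 higher and 184 lower in LEGSKO epithelia, 280 and 220 in LEGSKO fibers, and 39 and 31 for LEGSKO+BSO against LEGSKO fibers. DESeq2 also moved it for the differences (40 and 37 in LEGSKO, 141 and 165 in LEGSKO+BSO, where the majority turned in both) and the shared genes (96 and 46 in epithelia, 201 and 131 in fibers). The block moved it to 65 and 45 in LEGSKO epithelia, 111 and 32 in LEGSKO fibers, and 3 and 4 for the difference in LEGSKO. For LEGSKO+BSO against LEGSKO epithelia the block gave 26 and 20, where the majority turned from lower to higher. All 24 libraries gave 66 and 184 for LEGSKO+BSO against LEGSKO epithelia and 154 and 123 in LEGSKO fibers, and turned the majority in LEGSKO+BSO fibers (444 and 475). The 2-group fits gave 66 and 19 in LEGSKO fibers, and an adjusted p below 0.01 gave 36 and 5 shared in fibers. In LEGSKO+BSO against LEGSKO fibers, 3 higher and 1 lower became 4 and 3 with all 24 libraries, 30 and 26 with 2 groups, 7 and 7 with no filter, 2 and 0 thinned or with the block, and 1 and 0 with the stricter filter. With 19.3 to 46.6 M counts per library, genes below about 1 CPM, such as Ncf4, or Abcg1 in WT fibers, rest on few counts.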

Other observations

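Of the tests in this part, those of myeloid genes other than Csf3r and of the sign of 17 myeloid genes were chosen only after the result was seen.

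Some genes responded in both tissues. Of 13148 genes tested in both, 13 were called in the same direction in LEGSKO epithelia and LEGSKO fibers (9 higher, 4 lower), where independent lists would share 1.02, and 0 were called in opposite directions. Mt1 rose by a log2 of 2.24 in epithelia and 3.90 in fibers, Slc14a1 by 2.57 and 3.32, and Abcg1 by 0.82 and 3.12. The carbonic anhydrase Car2 (0.69 and 1.04), Pm20d1 (0.79 and 1.34), As3mt, an arsenic methyltransferase (0.55 and 0.87), Clrn1 (0.64 and 2.11), the kinesin Kif26a (1.15 and 1.33) and Csrp2 (0.40 and 0.47) also rose. Mkx (-1.90 and -2.68), Aplp1 (-0.80 and -0.71), Caprin2 (-0.50 and -0.59) and Wsb1 (-0.52 and -0.47) fell in both.

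In LEGSKO+BSO 28 genes were shared between the tissues (19 higher, 9 lower; 4.35 for independent lists), again 0 in opposite directions. The cholesterol exporter Abca1 rose by a log2 of 0.49 in epithelia and 1.40 in fibers, while the synthesis genes Fdft1 (-0.44 and -0.59), Hmgcs1 (-0.54 and -0.84) and the sterol sensor Insig1 (-0.64 and -0.76) fell in both. Higher in both were also Mt1 (2.78 and 4.04), Slc14a1 (2.71 and 3.30), G0s2, an inhibitor of fat breakdown (1.29 and 2.25), the laminin chain Lamb3 (1.11 and 2.44), Wnt5b (0.38 and 0.53) and Fn3k, which removes sugars from glycated proteins (0.63 and 0.49). Ikbke (-0.90 and -1.68) and Wsb1 (-0.87 and -0.94) fell in both. LEGSKO+BSO against LEGSKO shared 0 genes (edgeR; 0.00783 for independent lists). Across genes, which are not independent replicates, the responses of the tissues correlated at r = 0.270 in LEGSKO and 0.280 in LEGSKO+BSO.

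Transcripts of myeloid cells appeared in LEGSKO+BSO libraries. The 5 most deeply sequenced ones, LEGSKO+BSO fibers 1 to 4 and LEGSKO+BSO epithelia 4, held 5.45 to 9.39 CPM in sum of the 8 genes that drew notice. LEGSKO+BSO epithelia 2, with 20.5 M counts, held 6.33 CPM, of which Lyz2 was 4.32, and had the highest level of the leukocyte gene Ptprc (1.004 CPM), so the sum did not follow depth alone. LEGSKO+BSO epithelia 1 held 2.52 CPM and the other 17 libraries 0.263 to 1.52. Taken singly, Ccr2, Ncf4, Mmp8 and Ngp were higher in each of the 5 than in any other library, and Lyz2, Mpo, F13a1 and Hpgd were not. Ccr2 held at least 0.742 CPM in the 5 and at most 0.150 elsewhere, and Ncf4 0.516 and 0.0504. Summed counts in these 5 against the other 19 libraries were 249 against 14 for Ccr2, 154 against 1 for Ncf4, 24 against 0 for the neutrophil protease Ctsg, 18 against 2 for Prtn3, 11 against 2 for Elane and 21 against 3 for Hp. Reads of a myeloid sample from the same sequencing run, or myeloid cells in treated lenses, are candidate explanations. The lowest sum of 18 other bone marrow genes in the 5 libraries was 0.390 times the highest in the other 19, and LEGSKO+BSO epithelia 1 to 3 reached 0.910 times the highest WT or LEGSKO epithelial library. Csf3r made up a median of 86.0% of these sums. Without Csf3r the ratio among fibers was 0.199, while LEGSKO+BSO epithelia 4 held 2.15 CPM against at most 1.61 in the other epithelial libraries. The highest other fiber sum, 4.77 CPM, came from 2 genes in WT fibers 1, but the second highest, 1.33 CPM, also lay above the lowest LEGSKO+BSO fiber sum of 0.951 CPM. A few of the 17 genes were present elsewhere, with 135 counts of Ltf, 120 of Alox5ap and 81 of Cd177 in the other 19 libraries, so a small share would be hidden in these sums. By sign, 14 of the 17 genes were higher in LEGSKO+BSO fibers, as in 44 of 495 splits of the 12 libraries, so these genes alone do not settle whether myeloid RNA was present there. Over all genes with at least 12 counts there, 29 were higher in each LEGSKO+BSO fiber library than in any other fiber library and over 4-fold in mean. They include Mpo (51 counts against 0) and Ngp (49 against 0), but were picked for this difference and are no separate test. Reads of another sample and myeloid cells cannot be told apart by these sums or counts. In LEGSKO+BSO fibers against the other fibers, leukocyte transcripts stood at 0.0439 against 0.0185 CPM for Tyrobp, 0.0386 against 0.0256 for Srgn, 0.0619 against 0.0608 for Fcer1g and 0.0492 against 0 for Cd74. Coro1a stood at 0.0451 against 0.00483, S100a8 at 0.106 against 0.00932 and S100a9 at 0.183 against 0. All 7 lay below Ccr2, at 1.12 ± 0.296 CPM (SD, n = 4).

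Splitting the 8 libraries of each comparison in all 35 ways gave the real split alone as many genes (1 of 35 in each). This is the smallest share that 35 splits can give, and the comparisons of a tissue share libraries. Chance is thus made less likely for each gene count, but is not excluded. The highest other split called 4 genes beside the 127 of LEGSKO against WT epithelia, 7 beside 177 for LEGSKO+BSO against WT epithelia and 2 beside 109 for LEGSKO+BSO against LEGSKO epithelia. In fibers it called 40 beside 220, 18 beside 742 and 0 beside 4. For the numbers of lists chance cannot be excluded in any comparison. In epithelia 2 of 35 splits gave at least the 11 lists of LEGSKO against WT (highest other 11), 16 at least the 5 of LEGSKO+BSO against WT (highest other 9) and 28 at least the 3 of LEGSKO+BSO against LEGSKO (highest other 8). In fibers 18 gave at least 4 (highest other 7), 3 at least 8 (highest other 9) and 18 at least 3 (highest other 9).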
